A study of Mus musculus with 12 samples.

How the data were processed

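RNA was measured by sequencing in RAW 264.7 cells, a mouse macrophage line, in 12 libraries that fall into 4 groups of 3. Per the labels' protocols, cells received 20 uM of an agent named PSTO or vehicle for 30 minutes, then LPS at 500 ng/mL where the group has it, and were harvested after 6 h. The labels do not spell out PSTO, and the series title speaks of garlic extract. The groups are control, PSTO, LPS, and PSTO with LPS (PSTO+LPS). The labels number the replicates and call them triplicates, but do not say that they were separate cultures. The p-values therefore measure the spread between these samples.

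The deposited table gives whole-number read counts per gene, and per the submitters' processing notes HISAT and DESeq2 were used with the mouse build mm39. Total RNA was extracted with a Qiagen kit and sequenced on a standard Illumina workflow, per the labels' protocols. The read counter, the annotation release, the strand setting, the filters and the tool versions are not given in the sources used here. The deposited counts carry no normalization, which was checked on the values: all are whole numbers and the totals differ between libraries. The table holds 55137 entries, each with an Ensembl gene identifier and a symbol except 1336 unnamed loci. All 12 columns matched a sample. The annotation held here is of another mouse build, so it served only to mark pseudogenes, and no coordinates are given. Older symbols were matched through a list of gene synonyms.

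Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passing filterByExpr were kept, which left 14505 genes, 468 of them unnamed loci, and set aside 40632. The tested genes held at least 99.91% of the reads of every library. Library sizes were scaled by TMM, and each gene was fitted with a quasi-likelihood negative binomial model with 1 mean per group over all 12 libraries. The common biological coefficient of variation was 0.0959. The 5 comparisons were LPS vs control, PSTO+LPS vs PSTO, PSTO vs control, PSTO+LPS vs LPS, and the interaction, which is the PSTO effect with LPS minus the PSTO effect without LPS. A gene was called at an edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) under 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Levels are TMM-scaled counts per 1000000 reads (CPM), given as mean ± SD over 3 libraries (n = 3).

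Totals were 26575919, 20652947 and 25338243 reads in control, 21847730, 22502284 and 23857202 in PSTO, 28625784, 24530712 and 22341924 in LPS, and 20424584, 15817880 and 20088844 in PSTO+LPS. Where a group held 0 reads of a gene, the fold is a lower bound against a floor of 3 reads over the group's libraries. Where it held 1 to 3 reads, the ratio of reads has an exact 95% binomial interval. Floors and intervals cover counting error only.

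The choices of test, comparisons, lists, named genes and most alternatives were made before the data were examined. The genes named are, per comparison, the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap between the 2 groups and whose mean was at least 5 CPM in the higher group. For the interaction the overlap condition was not set, and unnamed gene models and pseudogenes were passed over. To these come up to 4 called members of each list by size of change, or the 2 most abundant where none was called, and a panel of 22 genes: Tnf, Il1b, Il6, Il10, Ifnb1, Nos2, Ptgs2, Ccl2, Ccl5, Cxcl10, Nfkbia, Tlr4, Cd14, Hmox1, Nqo1, Gclm, Txnrd1, Slc7a11, Srxn1, Ddit3, Hspa1a and Mt1.

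The 32 lists held 528 members, 504 of them measured. They cover inflammatory cytokines, chemokines, the NF-kB family and its feedback, immediate early genes, interferon-stimulated genes, eicosanoid synthesis, nitric oxide and arginine, Toll-like receptor signalling, the inflammasome, NRF2 targets, the ATF4 stress response, endoplasmic reticulum (ER) chaperones, HSF1 heat shock genes, metal response, cholesterol synthesis, fatty acid synthesis, LXR targets, glycolysis, hypoxia, oxidative phosphorylation, DNA replication and G1/S, G2 and mitosis, p53 targets, alternative activation, MHC class I, MHC class II, the lysosome, macrophage identity, osteoclast markers, ribosomal proteins, mitochondrially encoded genes and nuclear non-coding RNA. A further 7 lists hold markers of T cells, B cells, fibroblasts, epithelium, neutrophils, endothelium and erythroid cells. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 32 lists of a comparison. Camera with an estimated correlation, and fry, were alternatives. Where a list's members called adjusted over the list alone are counted, Benjamini-Hochberg was applied within the list.

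The procedure was tested on simulated data drawn from each gene's mean over all libraries and from the sizes of the real libraries. Few genes were changed, 67, 66 and 64 per size of change in the fit of PSTO vs control, and no other group effect was set. In the real comparisons 17.1% to 62.9% of genes were called. The simulated shares called and false calls therefore do not give the rates of the real comparisons. In the simulated PSTO vs control comparison (14154 genes in the fit), 44.8%, 66.7% and 79.7% of genes changed by 0.5, 1 and 2 on the log2 scale were called, with 9 false among 134 calls. In the simulated interaction (14152 genes), the shares were 25%, 63.6% and 68.3%, with 4 false among 105 calls. Of 200 unchanged lists, camera gave 4% an unadjusted p under 0.05, and it called 10 of 10 lists shifted by 0.5. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.674, for interferon-stimulated genes. The simulation therefore does not show how camera with the preset correlation behaves on lists whose genes move together.

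The alternatives were relative log expression and upper-quartile factors, no filter beyond 1 read, a filter of 50 reads in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, a test against a 1.5-fold change (glmTreat), an adjusted p under 0.01, and each library left out in turn. Thinning to the shallowest library and leaving out unnamed loci were added after the data were seen. Tables were handled with the R package data.table (version 1.17.8) and plots drawn with matplotlib 3.10.9.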

Results

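Gene expression was compared in RAW 264.7 mouse macrophages that had received the agent PSTO at 20 uM, LPS at 500 ng/mL, both, or neither, with 3 libraries per group. LPS is a bacterial surface component that macrophages sense through the receptor encoded by Tlr4. Library totals ran from 15817880 to 28625784 reads. The first principal component held 70.3% of the variance of log2 CPM and the second 10.6%. Within a group the lowest Spearman correlation between libraries across genes was 0.988, between PSTO+LPS 1 and PSTO+LPS 3. PSTO+LPS 1 lay apart from its group on the fourth component (2.7% of the variance), at -38.89 against 21.58 and 30.67. The 10 most abundant genes took 5.84 ± 0.06% of the reads in control, 6.27 ± 0.17% in PSTO, 6.75 ± 0.09% in LPS and 7.79 ± 0.15% in PSTO+LPS (SD, n = 3). Mitochondrially encoded transcripts took 1.5 ± 0.09%, 1.47 ± 0.26%, 1.17 ± 0.1% and 1.28 ± 0.07% in the same order.

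The comparison of LPS with control asks what LPS did in the absence of PSTO. Cytokine, chemokine, interferon-stimulated and antigen presentation genes rose, and genes of DNA replication and mitosis fell. With an estimated correlation the list calls of interferon-stimulated and antigen presentation genes were lost, and the others held. Il1b, which encodes interleukin-1 beta, rose from 0.0521 ± 0.0902 CPM in control to 1705 ± 43.8 CPM in LPS, a log2 change of 14.73 (SE 0.15, adjusted p = 6.71e-22). Tnf rose from 32.1 ± 2.09 to 2260 ± 70.2 CPM, a log2 change of 6.14 (SE 0.09). Nos2, the inducible nitric oxide synthase gene, rose by 13.15 on the log2 scale to 467 ± 21.6 CPM, and Il1a by 13.03 to 908 ± 38.4 CPM. No read of Csf3 or Il6 was found in the control libraries. Csf3 was at least 5810-fold higher and Il6 at least 1599-fold higher in LPS, against the floor of 3 reads over the control libraries. Serpinb2 had 1 read in control, and its ratio was 7444 with a 95% counting interval of 1335 to 294100. Rsad2 rose from 17 ± 3.88 to 10810 ± 661 CPM, Ifit1 from 8.24 ± 3.65 to 3900 ± 113 CPM, and Acod1 from 15.3 ± 2.59 to 8242 ± 112 CPM. Ptgs2, which encodes cyclooxygenase-2, rose from 33.4 ± 1.53 to 3307 ± 103 CPM. The largest falls were in Ung, from 20.1 ± 0.806 to 0.235 ± 0.168 CPM, and in the sphingosine phosphate receptor gene S1pr1, from 64.1 ± 3.01 to 1.07 ± 0.152 CPM. Hpgd fell by 5.13 on the log2 scale, Cxcr4 by 4.91 and Nt5e by 4.62. Tlr4 itself fell from 143 ± 4.1 to 43.9 ± 3.59 CPM, while Cd14, its co-receptor gene, rose from 1156 ± 50.1 to 2152 ± 45.5 CPM.

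At an edgeR adjusted p under 0.05, 9121 of 14505 genes (62.9%) differed between LPS and control, 4753 higher and 4368 lower. Of these, 2014 were at least 2-fold higher and 1848 at least 2-fold lower. Upper-quartile scaling moved the median of all genes by -0.15 on the log2 scale and the share of calls that were higher from 52.1% to 41.8%, and the filter of 50 reads gave 4159 higher and 4197 lower, so the balance of rises and falls depends on processing. Of the 22 panel genes, 21 were called, 18 higher and 3 lower. Camera called 15 of 32 lists, 12 higher and 3 lower, and 8 of the 15 calls held with an estimated correlation. All 20 measured cytokines were higher, Csf2 among them (adjusted p = 3.52e-12 for the list), as were all 15 chemokines, such as Ccl5 with a log2 change of 9.91 (adjusted p = 1.66e-09), and all 18 NF-kB genes, such as Tnfaip3 with 5.36 and Nfkbiz with 5.67 (adjusted p = 4.23e-13). Adjusted over the list alone the counts were also 20, 15 and 18. Of 14 immediate early genes 9 were higher and 2 lower, with Ier3 and Zfp36 among the rises, and the counts adjusted over the list alone were the same (adjusted p = 0.000607 for the list). Of 10 nitric oxide and arginine genes 8 were higher and 1 lower (adjusted p = 0.000293), and of 19 Toll-like receptor genes 15 were higher, Tlr2 among them, and 4 lower (adjusted p = 0.00179). These 6 calls held with an estimated correlation, as did those of both cell cycle lists.

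All 25 interferon-stimulated genes were higher with LPS, both over all genes and adjusted over the list alone (camera adjusted p = 1.04e-15; adjusted p = 0.169 with an estimated correlation). Gbp5 rose by 10.74 on the log2 scale and Rsad2 by 9.32. All 12 MHC class I genes were higher, including Tap1 with a log2 change of 4.71 (adjusted p = 5.34e-08 for the list; adjusted p = 0.179 with an estimated correlation). Of 9 MHC class II and co-stimulation genes 5 were higher, and Cd40 rose from 1.06 ± 0.544 to 480 ± 21.1 CPM (adjusted p = 0.0236 for the list; adjusted p = 0.0977 with an estimated correlation). All 19 DNA replication genes fell, with Cdc6 down from 21.2 ± 1.01 to 1.72 ± 0.124 CPM and Rrm2 from 67.7 ± 1.59 to 7.69 ± 1.44 CPM (adjusted p = 5.1e-10 for the list). All 20 mitosis genes fell, and Mki67 went from 378 ± 41 to 113 ± 5.26 CPM (adjusted p = 6.05e-08 for the list). Of 27 ribosomal protein genes 26 were slightly higher, with a median log2 change of 0.35 (adjusted p = 6.6e-06; adjusted p = 0.238 with an estimated correlation). Of 21 ATF4 genes 13 were higher and 5 lower, Cth rising from 2.57 ± 0.523 to 14.6 ± 1.84 CPM (adjusted p = 0.0236 for the list; adjusted p = 0.238 with an estimated correlation). Of 15 heat shock genes 11 were higher and 2 lower, Hspa1b among the rises (adjusted p = 0.00319; adjusted p = 0.181 with an estimated correlation). Hspa1a and Hspa1b are near-identical copies whose reads could be split by the counting, so their values are uncertain. Of 12 fatty acid synthesis genes 8 fell, Scd2 by 2.27 and Elovl6 by 2.08, and 3 rose (adjusted p = 0.0329 for the list; adjusted p = 0.387 with an estimated correlation). Without the library PSTO+LPS 1 the adjusted p of that list was 0.0503.

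The comparison of PSTO+LPS with PSTO asks the same of cells pretreated with PSTO. Cytokine, chemokine, NF-kB and interferon-stimulated genes rose, and mitosis and DNA replication genes fell, with the interferon and DNA replication list calls lost with an estimated correlation. MHC class II (adjusted p = 0.093), ATF4 (0.241) and fatty acid synthesis genes (0.144) were not called as lists. Il1b rose by 11.38 on the log2 scale (SE 0.12), Il1a by 11.88, Csf3 by 13.43 and Gbp5 by 11.75, and Rsad2 rose from 5.75 ± 1.11 to 11810 ± 1630 CPM. No read of Csf2 or U90926 was found with PSTO alone, and they were at least 500.5-fold and 676.4-fold higher with LPS added. Among the largest falls, S1pr1 went from 101 ± 3.09 CPM in PSTO to 2.5 ± 0.398 CPM in PSTO+LPS, Gpr183 from 85.1 ± 10.4 to 2.91 ± 1.43 CPM, and Cytip from 309 ± 37.8 to 15.4 ± 3.34 CPM. Rassf2, C5ar2 and Cnr2 were also among them. In all, 8662 genes were called (59.7%), 4318 higher and 4344 lower, with 1783 at least 2-fold higher and 1642 at least 2-fold lower. Upper-quartile scaling moved the median of all genes by -0.11 and the share of calls that were higher from 49.8% to 41.2%. More were higher than lower with relative log expression factors (4511 and 4177), DESeq2 (4555 and 4232), limma-voom (4316 and 4213) and the filter of 50 reads (4170 and 3880). The same held without PSTO 1 (4340 and 3888), PSTO 2 (4296 and 3850), PSTO 3 (4311 and 3845), PSTO+LPS 1 (4215 and 4146) or PSTO+LPS 2 (4099 and 4096). Of the 22 panel genes 18 were higher and 1 lower. Camera called 14 lists, 12 higher and 2 lower, and 6 calls held with an estimated correlation. All 20 cytokines (adjusted p = 6.54e-13), 14 of 15 chemokines (adjusted p = 7.69e-09) and all 18 NF-kB genes (adjusted p = 2.71e-14) were higher, with the same counts adjusted over the list alone. Immediate early genes (11 of 14 higher, 3 lower, adjusted p = 0.000641), nitric oxide genes (8 of 10 higher, 1 lower, adjusted p = 0.00051) and mitosis genes (20 of 20 lower, Cenpf by 2.83, adjusted p = 2.74e-09) kept their calls with an estimated correlation too. All 25 interferon-stimulated genes were higher (adjusted p = 4.01e-18; adjusted p = 0.144 with an estimated correlation), as were all 12 MHC class I genes (adjusted p = 2.83e-08; adjusted p = 0.185 with an estimated correlation). Of 19 DNA replication genes 15 were lower and 1 higher (adjusted p = 0.000115; adjusted p = 0.072 with an estimated correlation). Toll-like receptor genes (13 of 19 higher, 4 lower, adjusted p = 0.0051; adjusted p = 0.072 with an estimated correlation), heat shock genes (11 of 15 higher, 1 lower, adjusted p = 0.00489; adjusted p = 0.201 with an estimated correlation) and ribosomal protein genes (24 of 27 higher, adjusted p = 2.13e-07; adjusted p = 0.201 with an estimated correlation) were called higher. NRF2 targets, 14 of 24 higher with Sqstm1 and Txnrd1 among them and 5 lower, had adjusted p = 0.0339 (adjusted p = 0.582 with an estimated correlation), 0.1 without PSTO+LPS 1 and 0.058 without PSTO 1. Mitochondrially encoded genes, 12 of 15 higher, had adjusted p = 0.0292 (adjusted p = 0.508 with an estimated correlation), 0.0687 without PSTO 3 and 0.0502 without PSTO 2.

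The comparison of PSTO with control asks what PSTO did in unstimulated cells. Immediate early genes rose and DNA replication genes fell, and both list calls held with an estimated correlation. NRF2 targets of the oxidative stress response rose, and interferon-stimulated and cholesterol synthesis genes fell, but these 3 list calls were lost with an estimated correlation. The largest rise was in the phosphatase gene Dusp8, from 0.284 ± 0.195 CPM in control to 17.1 ± 0.833 CPM in PSTO, a log2 change of 5.92 (SE 0.36, adjusted p = 3.42e-10). Thbd (thrombomodulin) rose from 2.08 ± 0.594 to 21.2 ± 3.33 CPM and Procr, the endothelial protein C receptor gene, from 29.4 ± 3.45 to 250 ± 13.4 CPM, a log2 change of 3.09 (SE 0.08, adjusted p = 9.31e-15). The cytokine gene Osm rose from 8.47 ± 0.27 to 62.8 ± 1.9 CPM. Ptpn14, Nr4a3, Map1b and Usp39 complete the 8 largest rises, and Usp39 spread widely in PSTO (9.62 ± 5.99 CPM). The largest falls were in Ptchd1, with a log2 change of -2.30, and in Plau, the urokinase gene, from 65.9 ± 3.2 to 13.7 ± 4.13 CPM (log2 change -2.26, SE 0.13). Ifit1 fell from 8.24 ± 3.65 to 1.75 ± 0.481 CPM, Fam20c from 143 ± 7.5 to 36 ± 9.47 CPM, and Ighm from 52.3 ± 7.66 to 13.3 ± 2.35 CPM, and Hdac9, Hpgd and Oasl2 were the other falls of this size. In panel genes, Slc7a11, the cystine transporter gene, rose from 224 ± 19.5 to 659 ± 56 CPM, Nqo1 from 16.6 ± 2.33 to 38.1 ± 4.28 CPM, Srxn1 from 389 ± 8.38 to 861 ± 101 CPM and Hmox1, the heme oxygenase-1 gene, from 1759 ± 193 to 3112 ± 549 CPM. Cd14 rose from 1156 ± 50.1 to 3472 ± 170 CPM and Ptgs2 from 33.4 ± 1.53 to 90.8 ± 7.46 CPM. Il1b was called higher at a low level, 0.945 ± 0.102 CPM against 0.0521 ± 0.0902 CPM in control, a rise 1.68 times the highest level that reads carried over from PSTO+LPS libraries allow. Tnf (log2 change -0.13, adjusted p = 0.256), Ccl2 (-0.04, adjusted p = 0.927), Ccl5 (0.45, adjusted p = 0.17) and Tlr4 (-0.03, adjusted p = 0.836) were not called. Without PSTO 3 Tnf was called lower (adjusted p = 0.0101), and without control 3 Ccl5 was called higher (adjusted p = 0.0387).

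In PSTO vs control, 4440 genes (30.6%) were called, 2148 higher and 2292 lower, with 423 at least 2-fold higher and 294 at least 2-fold lower. Of the 22 panel genes 11 were higher and 4 lower. Camera called 16 lists, 8 higher and 8 lower, and 2 calls held with an estimated correlation, those of immediate early and of DNA replication genes. Of 14 immediate early genes 10 were higher and 2 lower (10 and 3 adjusted over the list alone), with Jun up from 35.3 ± 2.96 to 192 ± 0.625 CPM and Ier3 from 30.8 ± 3.5 to 158 ± 19.5 CPM (adjusted p = 1.17e-05 for the list). Of 19 DNA replication genes 17 fell, also adjusted over the list alone, with a median log2 change of -0.75 (adjusted p = 3.86e-11). Among them Mcm6 went from 188 ± 0.455 to 85.7 ± 4.89 CPM and Cdc6 from 21.2 ± 1.01 to 10.7 ± 0.731 CPM. Of 24 NRF2 targets 18 rose and none fell (19 adjusted over the list alone), with Prdx1 up from 1331 ± 51.2 to 2802 ± 120 CPM (adjusted p = 3.7e-09 for the list; adjusted p = 0.211 with an estimated correlation). Of 25 interferon-stimulated genes 19 fell and none rose (20 lower adjusted over the list alone), with a median of -1.15, and Usp18 went from 23.7 ± 5.97 to 6.18 ± 1.36 CPM (adjusted p = 7.19e-11 for the list; adjusted p = 0.243 with an estimated correlation). Of 23 cholesterol synthesis genes 18 fell and 3 rose, also adjusted over the list alone, with Lss down from 72.2 ± 3.95 to 35.9 ± 2.56 CPM and Mvk from 23.8 ± 1.87 to 11.4 ± 2.18 CPM (adjusted p = 9.52e-08 for the list; adjusted p = 0.112 with an estimated correlation). Of 12 fatty acid synthesis genes 8 fell and 1 rose, Scd1 by 1.10 and Fads2 by 0.68 among the falls (adjusted p = 0.00118 for the list; adjusted p = 0.223 with an estimated correlation). Of 20 mitosis genes 16 fell (18 adjusted over the list alone), Cenpf and Ccnb1 among them (adjusted p = 1.17e-05; adjusted p = 0.134 with an estimated correlation).

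Stress and surface lists changed as well with PSTO alone. Of 21 ATF4 genes 13 rose and 5 fell (14 and 5 adjusted over the list alone), with Ddit4 up from 5.51 ± 0.616 to 24.5 ± 1.72 CPM and Atf5 from 75.7 ± 3.49 to 151 ± 4.36 CPM (adjusted p = 0.000175 for the list; adjusted p = 0.134 with an estimated correlation). Of 15 heat shock genes 9 rose and 2 fell, with Hspa1a at 3.7 ± 0.494 CPM against 0.468 ± 0.245 CPM in control and Hsph1 at 427 ± 8.18 CPM against 238 ± 3.3 CPM (adjusted p = 0.000443 for the list; adjusted p = 0.149 with an estimated correlation). Of 19 ER chaperone genes 10 rose, Syvn1 and Herpud1 among them, and 2 fell, such as Edem1 (adjusted p = 0.0138; adjusted p = 0.252 with an estimated correlation). Of 12 MHC class I genes 7 fell (8 adjusted over the list alone), Psmb9 by 1.38 and Tap1 by 0.90 (adjusted p = 0.00118; adjusted p = 0.381 with an estimated correlation). Of 9 MHC class II and co-stimulation genes 4 rose, Cd80 from 6.87 ± 1.56 to 30.7 ± 2.66 CPM and Cd40 from 1.06 ± 0.544 to 2.56 ± 0.532 CPM (0.0871 with limma-voom for Cd40; adjusted p = 0.0227 for the list; adjusted p = 0.134 with an estimated correlation). Of 18 macrophage identity genes 9 fell and 3 rose (10 and 4 adjusted over the list alone), with Adgre1 down from 131 ± 1.67 to 72.2 ± 3.95 CPM and Fcgr1 from 32.9 ± 1.08 to 13.7 ± 3.13 CPM (adjusted p = 0.0204; adjusted p = 0.191 with an estimated correlation). Of 10 osteoclast markers 5 fell, Tnfrsf11a from 172 ± 8.67 to 68.9 ± 3.81 CPM (adjusted p = 0.0256 for the list; adjusted p = 0.134 with an estimated correlation), and the list's adjusted p was 0.0655 without PSTO 2. Of 12 p53 targets 8 rose, Pmaip1 from 35.6 ± 1.08 to 101 ± 10.9 CPM, and 2 fell (adjusted p = 0.0437 for the list; adjusted p = 0.37 with an estimated correlation). The p53 call was lost without control 3 (0.0507), PSTO 2 (0.0658), PSTO 3 (0.0997), LPS 1 (0.0504), LPS 2 (0.0507) or LPS 3 (0.0524). Of 20 cytokines 5 rose, Lif from 2.79 ± 0.722 to 11.6 ± 1.31 CPM among them, and 2 fell (adjusted p = 0.0454 for the list; adjusted p = 0.243 with an estimated correlation). The cytokine call was lost without control 3 (0.0882), PSTO 1 (0.0502), PSTO 3 (0.0599), LPS 1 (0.0526), LPS 3 (0.0543), PSTO+LPS 1 (0.0623), PSTO+LPS 2 (0.0555) or PSTO+LPS 3 (0.0581). Of 15 chemokines 3 rose, with Cxcl2 up from 13.4 ± 2.8 to 65 ± 7.91 CPM and Ccl4 from 3.59 ± 0.934 to 8.04 ± 0.901 CPM, and Cxcl10 fell from 2 ± 0.599 to 0.573 ± 0.41 CPM (adjusted p = 0.16 with limma-voom), but the list was not called (adjusted p = 0.222).

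**Figure D1:**
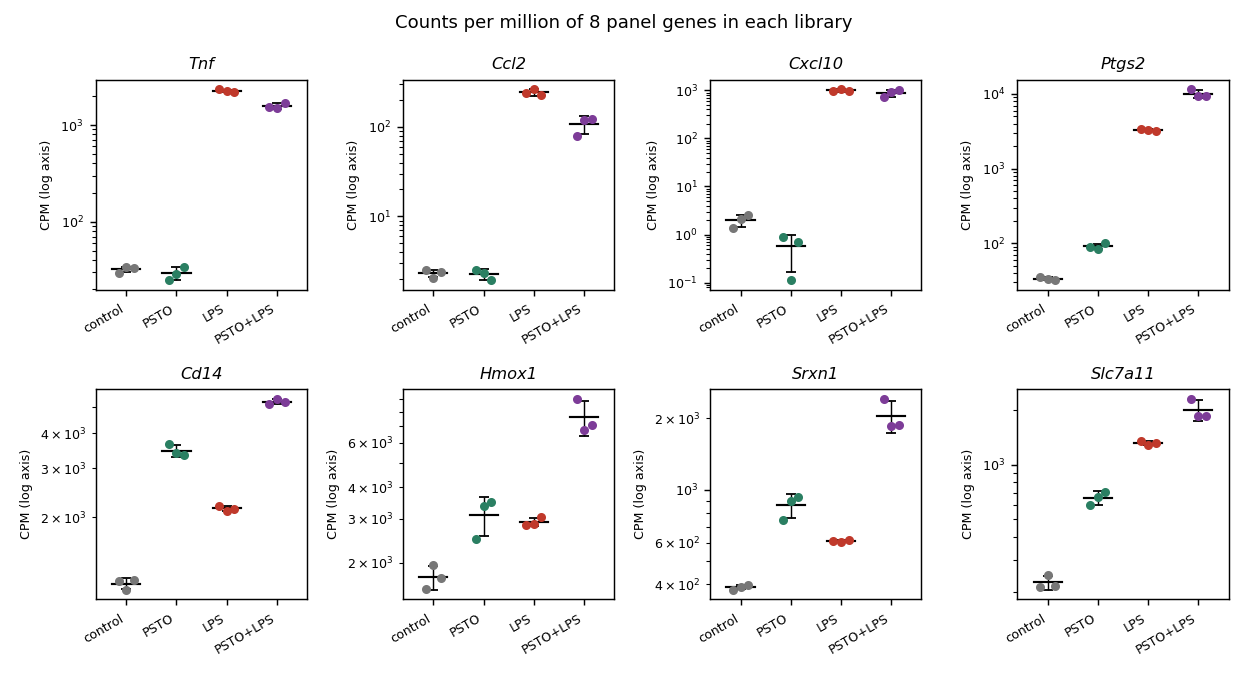
CPM on a log axis of 8 panel genes in each of the 12 libraries, by group, with points for libraries, a line for the mean and bars for 1 SD. Tnf lay at 32.1 CPM in control and 2260 CPM in LPS, and Hmox1 was highest in PSTO+LPS, at 7603 CPM.

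The comparison of PSTO+LPS with LPS asks whether PSTO changed the expression of LPS-treated cells. Cytokine genes went both ways: Osm, Lif, Il6 and Il1b rose, and Tnf and Ccl2 fell. Oxidative stress genes rose, and MHC class I, mitosis and osteoclast genes fell, but none of these list calls held with an estimated correlation. Tnfsf4, which encodes OX40 ligand, rose from 7.54 ± 0.854 CPM in LPS to 167 ± 18.4 CPM in PSTO+LPS, a log2 change of 4.48 (SE 0.16, adjusted p = 2.43e-13). Osm rose from 34 ± 4.77 to 470 ± 19.3 CPM (log2 change 3.79, SE 0.08, adjusted p = 1.54e-16), Thbd from 10.1 ± 1.54 to 152 ± 7.31 CPM, and Il23a from 3.18 ± 0.915 to 27 ± 2.11 CPM. Dusp8, Ptpn14, Il1f9 and Fosb complete the 8 largest rises. Lad1 fell from 6.56 ± 1.52 to 0.452 ± 0.339 CPM, the collagen gene Col5a3 from 552 ± 44.9 to 56.5 ± 20.7 CPM (log2 change -3.29, SE 0.18, adjusted p = 1.04e-10), the chemokine gene Ccl22 from 474 ± 14.8 to 88.3 ± 15.4 CPM, and the cyclin gene Ccnd2 from 25.7 ± 3.01 to 4.03 ± 1.78 CPM. Gpc1, Oaf, Ocstamp and Hdac9 complete the 8 largest falls. Il6 rose from 55.2 ± 8.5 to 154 ± 6.01 CPM (log2 change 1.48, adjusted p = 4e-09), Ptgs2 from 3307 ± 103 to 10110 ± 1233 CPM, and Il1b from 1705 ± 43.8 to 2535 ± 101 CPM (log2 change 0.57, adjusted p = 1.01e-06). Tnf fell from 2260 ± 70.2 to 1577 ± 100 CPM (log2 change -0.52, SE 0.07, adjusted p = 1.01e-05), Ccl2 from 242 ± 18.9 to 108 ± 23.9 CPM, and Nos2 from 467 ± 21.6 to 355 ± 89.5 CPM (adjusted p = 0.0132), with 251.6 CPM in PSTO+LPS 1 against 412.5 and 400.1 CPM in the other libraries of its group. Ccl5 (adjusted p = 0.96), Cxcl10 (0.295), Ifnb1 (0.576), Il10 (0.53) and Nfkbia (0.278) were not called. With no filter Cxcl10 was called lower (adjusted p = 0.00256).

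In PSTO+LPS vs LPS, 5557 genes (38.3%) were called, 2405 higher and 3152 lower, with 657 at least 2-fold higher and 516 at least 2-fold lower. The excess of falls depends on processing: upper-quartile scaling gave 2735 higher and 2797 lower, the filter of 50 reads 2668 and 2676, and a fit of only the groups compared 2565 and 2596. Of the 22 panel genes 11 were higher and 5 lower. Camera called 11 lists, 6 higher and 5 lower, and 0 of the calls held with an estimated correlation. Of 24 NRF2 targets 20 rose and none fell (21 adjusted over the list alone), with Srxn1 up from 610 ± 5.6 to 2048 ± 318 CPM, Hmox1 from 2910 ± 112 to 7603 ± 1210 CPM and Nqo1 from 11.9 ± 0.648 to 36.6 ± 2.87 CPM (adjusted p = 7.24e-12 for the list; adjusted p = 0.241 with an estimated correlation). Of 20 mitosis genes 18 fell, also adjusted over the list alone, with a median of -0.82, and Cenpf went from 24.6 ± 4.55 to 7.61 ± 0.979 CPM (adjusted p = 5.1e-08 for the list; adjusted p = 0.0986 with an estimated correlation). Of 19 DNA replication genes 10 rose and 2 fell, also adjusted over the list alone, with a median of 0.33, and E2f1 went from 4.53 ± 0.47 to 11.6 ± 1.97 CPM and Cdc6 from 1.72 ± 0.124 to 3.35 ± 0.196 CPM (adjusted p = 0.00741 for the list; adjusted p = 0.269 with an estimated correlation). Of 12 MHC class I genes 11 fell, also adjusted over the list alone, with Tap2 down from 128 ± 8.27 to 54.9 ± 13.1 CPM and Psmb10 from 262 ± 15.2 to 113 ± 25.6 CPM (adjusted p = 4.28e-05 for the list; adjusted p = 0.393 with an estimated correlation). Of 19 ER chaperone genes 13 rose, Dnajb9 among them, and 2 fell (15 and 2 adjusted over the list alone; adjusted p = 4.28e-05; adjusted p = 0.172 with an estimated correlation). Of 10 osteoclast markers 8 fell and 1 rose, also adjusted over the list alone, with Nfatc1 down from 270 ± 19.7 to 103 ± 7.75 CPM and Mmp9 from 72.2 ± 3.96 to 22.9 ± 4.3 CPM (adjusted p = 0.000776 for the list; adjusted p = 0.0986 with an estimated correlation). Of 23 cholesterol synthesis genes 14 fell and 3 rose, Mvk by -1.45 on the log2 scale (adjusted p = 0.00342 for the list; adjusted p = 0.292 with an estimated correlation).

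Immediate early genes rose with PSTO in LPS-treated cells too, 8 of 14 with 1 lower (10 and 1 adjusted over the list alone), and Jun went from 25.1 ± 4.81 to 137 ± 6.68 CPM (adjusted p = 0.00485 for the list; adjusted p = 0.0986 with an estimated correlation). Of 15 heat shock genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), Hsp90aa1 from 1285 ± 26.4 to 2261 ± 190 CPM (adjusted p = 0.0072 for the list; adjusted p = 0.292 with an estimated correlation). Of 25 interferon-stimulated genes 16 fell and none rose, also adjusted over the list alone, with Gbp5 down from 480 ± 21.3 to 190 ± 52.3 CPM and Oasl2 from 684 ± 10.3 to 331 ± 70.8 CPM (adjusted p = 0.0442 for the list; adjusted p = 0.784 with an estimated correlation; 0.138 with fry). That list call was lost without PSTO+LPS 1 (0.182), LPS 1 (0.0513), LPS 2 (0.0713) or LPS 3 (0.0603). Of 27 ribosomal protein genes 10 rose slightly, Rpl10a among them (adjusted p = 0.0165 for the list; adjusted p = 0.658 with an estimated correlation; 0.0519 without PSTO+LPS 2). Of 20 cytokines 8 rose and 8 fell (9 and 8 adjusted over the list alone), with Lif up from 402 ± 27.7 to 1961 ± 75.7 CPM and Csf2 from 3.75 ± 0.639 to 18.4 ± 2.66 CPM, and the list was not called (adjusted p = 0.433). Its median, -0.02, and its mean, 0.46, differed in sign. Of 15 chemokines 3 rose, Cxcl2 and Cxcl3 among them, and 6 fell (adjusted p = 0.433). Of 18 NF-kB genes 3 rose and 6 fell, Tnfaip3 from 489 ± 0.379 to 272 ± 18.8 CPM (adjusted p = 0.361 for the list), and of 19 Toll-like receptor genes 4 rose, Cd14 from 2152 ± 45.5 to 5208 ± 107 CPM, and 9 fell (adjusted p = 0.398).

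The interaction asks whether the PSTO effect differed between LPS-treated and unstimulated cells. The difference was clearest for DNA replication genes, which fell with PSTO alone and of which more rose than fell with PSTO in LPS-treated cells. In all, 2476 genes (17.1%) were called, 1010 with a higher and 1466 with a lower PSTO effect under LPS, and of 22 panel genes 3 and 5. Which direction prevailed depends on processing: upper-quartile scaling gave 1199 higher and 1245 lower, and the filter of 50 reads 1391 and 1168. The majority also turned without control 1 (1123 and 990), control 2 (1161 and 1000), control 3 (1070 and 1015), PSTO 1 (1088 and 1005), PSTO 2 (1080 and 999) or PSTO 3 (1168 and 993). Camera called 17 lists, 12 higher and 5 lower, and only the DNA replication call held with an estimated correlation. Of the 19 DNA replication genes 15 had a higher PSTO effect under LPS and none a lower one (16 adjusted over the list alone; list adjusted p = 6.65e-17). E2f1 had an interaction of 2.03 (SE 0.19, adjusted p = 4.26e-07) and Cdc6 of 1.95 (SE 0.21). Of 25 interferon-stimulated genes 15 were higher and 1 lower (18 and 1 adjusted over the list alone), with Ifit1 at 1.73 (adjusted p = 0.128 with limma-voom) and Rsad2 at 1.69 (list adjusted p = 2.9e-06; adjusted p = 0.387 with an estimated correlation). Lower were 11 of 21 ATF4 genes, such as Trib3 (list adjusted p = 0.000341; adjusted p = 0.235 with an estimated correlation), 9 of 20 mitosis genes, such as Cenpf and Cdk1 (list adjusted p = 0.00152; adjusted p = 0.235 with an estimated correlation), and 6 of 15 chemokines with 1 higher, Ccl22 by -2.52 (list adjusted p = 0.0163; adjusted p = 0.324 with an estimated correlation). Higher were 4 of 12 fatty acid synthesis genes (list adjusted p = 0.00274), 8 of 19 ER chaperone genes with 1 lower (0.00637), 10 of 18 macrophage identity genes with 3 lower, Cebpa among the higher (0.00954), and 6 of 23 lysosome genes with 2 lower, Gla among the higher (0.00982). With an estimated correlation these 4 lists had adjusted p = 0.235, 0.235, 0.235 and 0.387. NRF2 targets were higher for 7 of 24 and lower for 2 (11 and 2 adjusted over the list alone), Srxn1 by 0.60 and Hmox1 by 0.56 (list adjusted p = 0.00905; adjusted p = 0.488 with an estimated correlation; 0.13 with fry). The remaining 7 list calls were lost when single libraries were left out. They were mitochondrially encoded genes (0.0261), immediate early genes (0.0401), eicosanoid synthesis (0.0401), alternative activation (0.0401), MHC class II (0.0401), cholesterol synthesis (0.0408) and ribosomal proteins (0.045), with adjusted p = 0.459, 0.235, 0.235, 0.235, 0.235, 0.387 and 0.595 with an estimated correlation. Mitochondrial genes were lost without control 2 (0.0587), PSTO 3 (0.0764) or LPS 1 (0.0627), immediate early genes without LPS 1 (0.0575), and eicosanoid genes without control 1 (0.0511), control 2 (0.0532), PSTO 1 (0.0747) or PSTO+LPS 1 (0.0719). Alternative activation was lost without control 2 (0.0569), control 3 (0.0613), PSTO 1 (0.0696), PSTO 2 (0.074), PSTO 3 (0.0699) or PSTO+LPS 2 (0.0633), and MHC class II without LPS 3 (0.0628) or PSTO+LPS 3 (0.0673). Cholesterol synthesis was lost without PSTO 1 (0.0701), LPS 1 (0.0575) or PSTO+LPS 3 (0.0673), and ribosomal proteins without LPS 1 (0.0808), LPS 3 (0.0621), PSTO+LPS 2 (0.1) or PSTO+LPS 3 (0.0673).

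**Figure D2:**
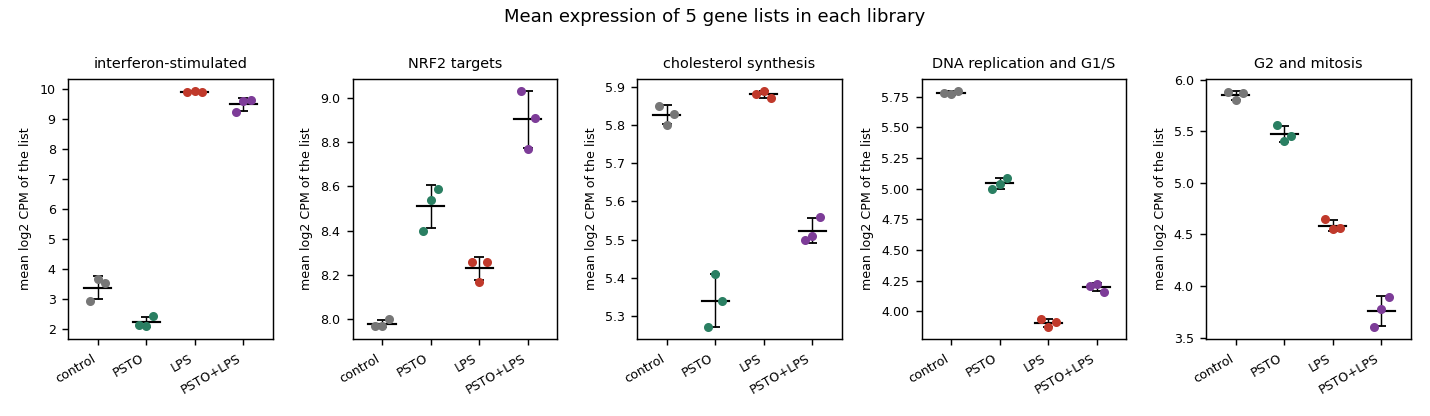
Mean log2 CPM of 5 gene lists in each of the 12 libraries, by group, with points for libraries, a line for the mean and bars for 1 SD. The DNA replication list fell from 5.78 in control to 5.04 in PSTO and stood at 3.91 in LPS and 4.2 in PSTO+LPS, whereas the mitosis list was lowest in PSTO+LPS, at 3.76.

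The LPS response was compared with and without PSTO over the 3862 genes at least 2-fold changed in LPS vs control. The slope through the origin of the response with PSTO on that without was 0.861 (pooled jackknife SE 0.067), with r = 0.919 across genes, which are not independent replicates, and the same sign for 97.05%. The jackknife pooled the left-out libraries of all groups around 1 mean, and genes were filtered and chosen anew each time. Its SE therefore also holds differences between groups and gene sets, and does not measure the spread between libraries alone. Simulations with no PSTO effect gave slopes from 0.955 to 0.970 in 10 runs, so choosing genes on the response itself lowered the slope. Genes chosen on PSTO+LPS vs PSTO gave 0.953, against 0.990 to 1.005 in the simulations. With these genes and the axes exchanged, the response without PSTO on that with PSTO had a slope of 0.9135, also under 1. For the 3862 genes the exchanged slope was 0.992. No simulated range is given for the exchanged axes. Scatter between genes lowers a slope in either direction, so these slopes alone do not show that PSTO weakened the LPS response. Of the 2014 genes raised at least 2-fold by LPS, 730 were lower and 351 higher in PSTO+LPS than in LPS, such as Ccl22 and Col5a3 among the lower and Il6 and Ptgs2 among the higher. Independent lists of these sizes would share 437.7 and 333.9, and simulations with no PSTO effect gave at most 1 and 0. With no gene changed by PSTO few calls can arise, so these simulated counts do not test the imbalance of 730 against 351. The choice uses the same LPS libraries as the test. Among the 1783 genes raised at least 2-fold in PSTO+LPS vs PSTO the counts were 508 lower and 458 higher, against 387.5 and 295.6 for independent lists. Of the 1848 genes lowered at least 2-fold by LPS, 309 were lower and 385 higher in PSTO+LPS than in LPS, against 401.6 and 306.4, and of the 1642 lowered in PSTO+LPS vs PSTO 499 were lower and 162 higher, against 356.8 and 272.3. In PSTO vs control, 471 of the 2014 genes were higher and 369 lower, against 298.2 and 318.2 for independent lists, with the control libraries shared. Of the 1783 genes 349 were higher and 360 lower, against 264 and 281.7, with the PSTO libraries shared. Of the 1848 lowered genes 150 were higher and 557 lower with PSTO alone, against 273.7 and 292, and of the 1642 lowered genes 192 and 423, against 243.2 and 259.5. The same libraries are shared here, and sharing can itself move such counts away from those of independent lists. The simulations did not cover these overlaps with PSTO alone, so the excesses do not show that the effects of LPS and PSTO resemble each other. The PSTO effects with and without LPS share no library: 1173 genes rose in both, against 356.1 for independent lists, 1373 fell in both, against 498.1, and 303 changed in opposite directions. Thbd, Osm, Dusp8 and Ptpn14 were among those that rose in both.

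**Figure D3:**
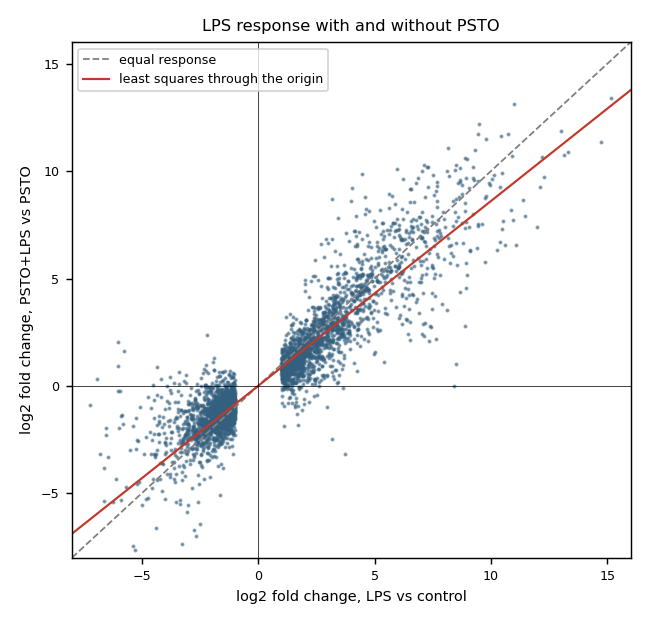
Log2 fold change of PSTO+LPS vs PSTO (vertical axis) against that of LPS vs control (horizontal axis) for the 3862 genes at least 2-fold changed in LPS vs control, 1 point per gene, with a dashed line of equal response. The solid line has the slope of 0.861.

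Camera called 7 lists in no comparison, while fry, which does not compare a list with other genes, called all 7 in LPS vs control (adjusted p from 8.13e-10 to 0.0439). Inflammasome genes were higher with LPS in 7 of 11, Nlrp3 from 116 ± 6.65 to 1502 ± 6.5 CPM and Casp4 among them, and lower in 2 (list adjusted p = 0.0698), and with PSTO in LPS-treated cells 3 rose and 5 fell, Gsdmd from 208 ± 12.7 to 89.2 ± 14.4 CPM (list adjusted p = 0.212). Of 16 glycolysis genes 9 were higher and 4 lower with LPS (list adjusted p = 0.0776), and of 14 hypoxia genes 7 and 5 (0.434). With PSTO, Pfkfb3 rose in LPS-treated cells from 66 ± 5.5 to 210 ± 15.1 CPM, and Vegfa rose both with LPS, from 133 ± 5.11 to 378 ± 7.16 CPM, and without, from 77 ± 5.59 to 236 ± 12.1 CPM. Of 4 metal response genes 3 rose with LPS (list adjusted p = 0.0612), and Mt1 fell with PSTO in LPS-treated cells from 284 ± 13.1 to 170 ± 21.7 CPM. Of 9 LXR targets 2 rose and 4 fell with PSTO alone (list adjusted p = 0.335), Abca1 rising from 36.8 ± 3.94 to 138 ± 19.1 CPM. Of 24 oxidative phosphorylation genes 7 were higher and 3 lower with LPS (list adjusted p = 0.574), and of 4 measured nuclear non-coding RNAs 2 were lower (0.324). Markers of other cell types were scarce. Summed over a list, T cell markers ran from 1.08 to 7.56 CPM per library, mostly Lck, B cell markers from 0 to 12 CPM, mostly Pax5, neutrophil markers from 1.31 to 11.7 CPM, mostly S100a8, and endothelial markers from 1.12 to 5.36 CPM, with Cdh5 highest. The mean of B cell markers was 0.0533 CPM in control, 0.348 in PSTO, 9.67 in LPS and 5.89 in PSTO+LPS, and that of neutrophil markers 1.73, 1.64, 3 and 9.97 CPM. T cell markers had means of 1.64, 2.38, 6.81 and 5.22 CPM and endothelial markers of 1.35, 1.57, 3.92 and 4.2 CPM. Fibroblast markers reached 0.536 CPM, epithelial markers 0.234 CPM and erythroid markers 0.594 CPM at most.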

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

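The exchanges of PSTO labels were planned before the data were examined, and the tests on the 3 patterns that follow (carry-over, a trace of LPS, scaling, single libraries, variation between cultures and read numbers) were chosen only after the results were seen. Results are listed here because the effect of PSTO differed between LPS-treated and unstimulated cells, by edgeR's test of the interaction for genes and camera's for lists. The interaction called 2476 genes. Of 100 splits that exchange PSTO labels within unstimulated and within LPS-treated libraries, the real one included, 1 gave as many, and the highest of the others gave 1826. Splits that mix libraries with and without PSTO place the PSTO effect in the spread within groups. This lowers their calls with or without an interaction, so the exchange cannot decide whether the count arose from a random grouping. For each of the other 4 comparisons the 10 splits of 6 libraries are too few for a share under 0.05: the real splits gave 9121 genes in LPS vs control, 8662 in PSTO+LPS vs PSTO, 4440 in PSTO vs control and 5557 in PSTO+LPS vs LPS, each in 1 of 10 splits, and the highest other split gave 0 genes in each.

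Among genes, the interaction was largest upwards in Snrnp40 (4.58 on the log2 scale), Ung (3.14), Il23a (2.96), Gucy2g (2.81), Ccr3 (2.75), Apol9b (2.65), Hcar2 (2.60) and Slc5a3 (2.49). Slc5a3, an inositol transporter gene, stood at 110 ± 7.38 CPM in control, 118 ± 12.9 in PSTO, 14.6 ± 2.52 in LPS and 87.9 ± 14.8 in PSTO+LPS, and the niacin receptor gene Hcar2 at 1.22 ± 0.292, 0.723 ± 0.347, 120 ± 3.47 and 423 ± 18.9 CPM. It was largest downwards in Srcin1 (-4.29), Ccnd2 (-4.05), Gpc1 (-3.56), Il1b (-3.35), Ocstamp (-2.98), Bcl2a1a (-2.90), Txnrd2 (-2.65) and Src (-2.63). Src stood at 7.53 ± 1.06 CPM in control, 16.2 ± 1.3 in PSTO, 273 ± 8.13 in LPS and 94.2 ± 12.4 in PSTO+LPS. Srcin1, Bcl2a1a and Il1b had few reads in control, so the size of their interaction depends on the prior count. The interaction of Il1b also rests on its rise in PSTO alone, which was 1.68 times the highest level that reads carried over from PSTO+LPS libraries allow, so carry-over stays open for it. Apol9b and Bcl2a1a have near-identical copies, and Snrnp40 and Txnrd2 spread widely within groups. Of panel genes, the interaction was -0.39 in Tnf, -1.13 in Ccl2, 1.62 in Cxcl10, -0.31 in Cd14, 0.56 in Hmox1, -0.95 in Slc7a11 and 0.60 in Srxn1. Without 1 library the call was lost for Snrnp40 (adjusted p = 0.0654 without control 3), Ung (0.0597 without PSTO+LPS 1), Il23a (0.206 without control 1, 0.119 without control 2) and Ccr3 (0.18 without control 1, 0.0593 without PSTO+LPS 1). The same holds for Tnf (0.121 without control 1, 0.0571 without control 3, 0.073 without PSTO 2, 0.161 without PSTO 3) and Txnrd2 (0.0565 without control 1, 0.0732 without control 3, 0.0772 without PSTO 1, 0.0594 without PSTO+LPS 2, 0.0523 without PSTO+LPS 3). Bcl2a1a lost its call without control 1 (0.138), control 3 (0.131), PSTO 1 (0.181), PSTO 3 (0.104), LPS 1 (0.0591), LPS 2 (0.0589), LPS 3 (0.0667), PSTO+LPS 1 (0.0535) or PSTO+LPS 2 (0.0514).

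Among lists, the median interaction was 1.18 for DNA replication genes, 0.91 for interferon-stimulated genes, 0.53 for alternative activation, 0.31 for fatty acid synthesis, 0.27 for macrophage identity, 0.23 for NRF2 targets, 0.19 for eicosanoid synthesis, 0.19 for mitochondrially encoded genes, 0.16 for ER chaperones, 0.10 for cholesterol synthesis, 0.10 for the lysosome and 0.065 for ribosomal proteins. It was -0.74 for MHC class II, -0.73 for chemokines (-0.71 without 4 members at 3 reads or fewer in a group), -0.42 for mitosis genes, -0.35 for immediate early genes and -0.31 for ATF4 genes. With an estimated correlation only the DNA replication call held. Without single libraries 7 of the list calls were lost: mitochondrially encoded genes without control 2 (0.0587), PSTO 3 (0.0764) or LPS 1 (0.0627), immediate early genes without LPS 1 (0.0575), MHC class II without LPS 3 (0.0628) or PSTO+LPS 3 (0.0673), and cholesterol synthesis without PSTO 1 (0.0701), LPS 1 (0.0575) or PSTO+LPS 3 (0.0673). Eicosanoid synthesis was lost without control 1 (0.0511), control 2 (0.0532), PSTO 1 (0.0747) or PSTO+LPS 1 (0.0719), and ribosomal proteins without LPS 1 (0.0808), LPS 3 (0.0621), PSTO+LPS 2 (0.1) or PSTO+LPS 3 (0.0673). Alternative activation was lost without control 2 (0.0569), control 3 (0.0613), PSTO 1 (0.0696), PSTO 2 (0.074), PSTO 3 (0.0699) or PSTO+LPS 2 (0.0633).

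The first pattern concerns 282 genes raised at least 32-fold by LPS in both LPS comparisons. Of these, 21, such as Ptgs2, Cxcl2, Ccl4 and Lif, were also higher in PSTO alone than in control, while 52 were lower. Among all 14505 genes tested 2148 were higher and 2292 lower. Rises were less frequent among the 282, but a choice by the fold over PSTO disfavours genes that PSTO raised. The lower share of rises is therefore partly set by the choice and is not read as a trait of these genes. Of the 2014 genes raised at least 2-fold in LPS vs control 471 were higher and 369 lower. Some of the 21 had few reads, such as Il1bos with 5 and Acpp with 7 over the PSTO libraries. With limma-voom the calls of the members Il10 (adjusted p = 0.215), Ptger2 (0.0928) and Cd40 (0.0871) were lost. Reads carried over from LPS-treated libraries are argued against: the median rise over control of the members other than Il1b was 28.8 times the highest level that carry-over allows, a bound of 0.021% set by the 4 reads of Csf3 in PSTO. For Il1b the multiple was 1.68, too close to the bound to decide, so carry-over stays open for that gene. A trace of LPS as the only stimulus is argued against by 34 of the 423 genes at least 2-fold higher in PSTO than in control. These 34 were at least 2-fold lower in LPS than in control. Among all 14505 genes 1848 were that much lower in LPS, a larger share than among the 423. The argument fails if a trace acts on the 34 in the opposite direction to 500 ng/mL, which was not tested. A trace of LPS together with another effect of PSTO stays open, and an induction of these genes by PSTO itself remains a hypothesis that an LPS assay of the PSTO stock would test.

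The second pattern is that 19 of 25 interferon-stimulated genes, such as Ifit1 and Usp18, were lower in PSTO than in control. Reads carried over from LPS-treated libraries into control are argued against, since the median excess of control over PSTO was 57.7 times what carry-over allows. The choice of scaling is argued against, since 2 other scalings moved the median of all genes by at most 0.017 while the list median was -1.15. A single library is argued against by the list means in log2 CPM. They were 2.93, 3.65 and 3.51 in the control libraries and 2.13, 2.1 and 2.42 in the PSTO libraries. Camera's adjusted p was at most 1.45e-09 over 12 left-out libraries. It rests on the preset correlation, so it cannot decide this for genes that move together. Variation of the whole list between cultures stays open, because these genes move together (adjusted p = 0.243 with an estimated correlation), although the list means did not overlap (lowest in control 2.93, highest in PSTO 2.42). A lower basal interferon response with PSTO may be the cause and remains a hypothesis that a measurement of secreted interferon would test.

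The third pattern is that DNA replication genes fell with PSTO alone and not with PSTO in LPS-treated cells, where 10 rose, E2f1 and Cdc6 among them, and 2 fell (adjusted p = 0.00741 for the list; adjusted p = 0.269 with an estimated correlation). The choice of scaling is argued against, since 2 other scalings moved the median interaction of all genes by at most 0.039 while the list median was 1.18. Too few reads in the LPS libraries to show a fall are argued against by a median of 1153 reads per member over those libraries. A lower limit of expression that LPS alone reaches could hide a fall but would not give the rise of the 10 members. Such a limit as the cause of the missing fall, and a change in total RNA per cell, were not tested and stay open. An effect of PSTO on the entry into DNA replication that depends on LPS may be the cause, a hypothesis that counting the cells in each phase would test.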

How the results depend on the processing

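Thinning to the shallowest library and leaving out unnamed loci were tests chosen after the data were seen, and the others were planned. All counts of called genes stayed within 1.5 times the main count under other scalings, filters, tools, sets of groups, the replicate block, thinning and each left-out library. The exceptions are the stricter thresholds, which by construction call fewer genes: against a 1.5-fold change glmTreat called 4264 genes in LPS vs control, 3823 in PSTO+LPS vs PSTO, 581 in PSTO vs control, 978 in PSTO+LPS vs LPS and 284 in the interaction, with 243 LPS-raised genes lower and 125 higher with PSTO, and an adjusted p under 0.01 left 1471 in the interaction. Leaving out a library of the groups compared gave 8601 to 8707, 8146 to 8361, 3725 to 3926, 4790 to 5143 and 2079 to 2408 genes in the 5 comparisons, and leaving out a library of the other groups gave 9099 to 9353, 8624 to 8738, 4299 to 4802 and 5380 to 5549 in the first 4. The slope of the LPS response with against without PSTO ran from 0.808 to 0.8709 over left-out libraries, was 0.7947 with no filter and 0.9059 with the filter of 50 reads, and was 0.9525 with genes chosen on PSTO+LPS vs PSTO, which by construction moves the selection to the other comparison. No strong effect shared by replicate number was seen. The 18 correlations of same-numbered libraries ran from -0.031 to 0.051, and those of differently numbered libraries from -0.047 to 0.04. Of 12 libraries, 0 correlated best with their own number in all 3 other groups. A weak shared effect cannot be excluded, and the labels do not say what the number stands for. With the replicate block 8987, 8521, 4294, 5366 and 2345 genes were called, and the list calls of NRF2 targets in PSTO+LPS vs PSTO (0.0506) and of cholesterol synthesis (0.0559), alternative activation (0.0633) and ribosomal proteins (0.0633) in the interaction were lost. Fry, which does not compare a list with other genes, called 29, 31, 24, 20 and 20 lists, but not interferon-stimulated genes in PSTO+LPS vs LPS (0.138) or NRF2 targets (0.13), ribosomal proteins (0.131) and mitochondrially encoded genes (0.112) in the interaction, which camera called. With limma-voom 27 calls were lost among 724 entries of named genes over the 5 comparisons, not all of them listed here. In PSTO vs control they were those of Cxcl10 (0.16), Cd40 (0.0871), Il10 (0.215), Mx1 (0.196), Ptger2 (0.0928), Acod1 (0.114), Mt2 (0.0868), Fas (0.0505) and Psmb10 (0.0611). In the interaction they included those of Snrnp40 (0.166), Ung (0.072), Il23a (0.171), Ccr3 (0.0521), Apol9b (0.254), Bcl2a1a (0.111), Cxcl10 (0.286), Ccl2 (0.146) and Ifit1 (0.128). Interaction calls were also lost for Txnrd2 with DESeq2 (0.09), for Bcl2a1a with the replicate block (0.0563) and, when thinned, for Bcl2a1a (0.0608), Il23a (0.059) and Ccl2 (0.0607). The cause of these losses was not tested. The mitochondrial gene mt-Co1, not called in PSTO vs control (log2 change 0.02), was called lower without PSTO 1 (-0.179, adjusted p = 0.029) and stood at 0.076 without PSTO 2. Depth limits genes with few reads in control, such as Il6 and Csf3, whose folds are lower bounds.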
